A study of Mus musculus with 14 samples.

How the data were processed

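The study profiled cultured mouse neural stem cells from wild-type and Tet2 -/- forebrain. Tet2 is a dioxygenase that oxidises 5-methylcytosine to 5-hydroxymethylcytosine (5hmC) and onward. The labels list 14 samples in 8 groups, of which 8 are RNA-seq samples. The results use 3 deposited peak lists, which stand for 6 samples: 2 5hmC libraries per genotype and 1 Foxo3a chromatin immunoprecipitation (ChIP-seq) library per genotype, each from proliferating cells. RNA-seq values were not analysed here. Per the labels' protocols, neural stem and progenitor cells were isolated on a Percoll gradient and grown with FGF-2 and EGF. Chromatin for Foxo3a ChIP was fixed with formaldehyde and sonicated, and genomic DNA for 5hmC profiling was sonicated before further steps.

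Per the submitters' processing notes, the processing tools included CASAVA 1.4, Bowtie 0.12.9, TopHat2 2.0.8, Cuffdiff 2.2.1 and MACS 1.4.2, and the genome build was mm9. The role of each tool, the MACS threshold and any control library are not given in the sources used here. The authors deposited 1 5hmC list per genotype, with a position and a peak score for each peak. Each list was assigned to its genotype by the list's own name. Whether both libraries of a genotype were pooled before calling is not given in the sources used here. The score has no header. Its lowest value of 50 and the peak names match the p-value score on a minus 10 log10 scale that MACS writes, and it was used only to rank or filter peaks within a list. In the wild-type list 174 peaks sat at exactly 3100 and 42 above it, so the order of the very highest scores is not informative. The authors deposited the Foxo3a peaks of both genotypes as 1 merged list of positions without a score, and nothing in it says which genotype a peak came from. Read numbers and sequencing depth are not known from these lists, so no value was scaled to depth. A longer list can reflect deeper sequencing as well as more 5hmC.

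Peaks were compared by overlap, with at least 1 bp counted as shared. Peaks of 1 list did not overlap each other. Overlap was set against 1000 random rotations. In each, the Tet2 -/- 5hmC list or the Foxo3a list was shifted around every chromosome by a random distance, which keeps peak widths and spacing. The two-sided rotation p is a permutation p over positions. It compares these lists and not animals, and its smallest possible value is 0.002. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and take neighbouring peaks as independent. With 1 list per genotype there is no replicate error for any difference between genotypes, and no p-value was computed for differences in peak number. Loss and gain at Foxo3a peaks were given as odds ratios, also as Mantel-Haenszel odds ratios within deciles of score and of width, with intervals from leaving out each chromosome in turn (jackknife). Fold over rotation is the observed share divided by the mean share over rotations. Peak density was the number of peaks per Mb between the first and last peak of any list on a chromosome. The genome was also divided into 1 Mb windows. Windows with at least 50 peaks in either list were ranked by the log2 ratio of peak numbers with a pseudocount of 5.

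The rule for naming regions, set before the data were examined, took the 5 highest-scoring peaks of each 5hmC list, the 5 windows with the largest loss and the 5 with the largest gain, and the 5 windows with the most Foxo3a peaks. A gene annotation of mm9 was not used here, and coordinates were not converted between builds, so no gene is named and the gene lists, gene-body and genomic-feature comparisons that were planned were not run. Positions are mm9 and counted from 1. The alternatives were a stricter score, equal list lengths, merging of near peaks, autosomes only, other definitions of overlap, local shifts of 20 to 200 kb, and wider Foxo3a peaks. The comparison of Tet2 -/- peaks without a wild-type peak at Foxo3a, the direct comparison of both genotypes' overlap with Foxo3a, and the split of Foxo3a regions by their peak names were chosen after seeing the data.

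The rotation and odds ratio procedures were tested on simulated data built from the real peaks, with 20 simulations of 200 rotations each. For loss at Foxo3a peaks over 170335 peaks, a simulated odds ratio of 0.4 was recovered as 0.403 on average and called in 20 of 20 simulations, and an odds ratio of 1 was called in 0 of 20. For Foxo3a overlap over 21395 regions, 10 added percentage points were recovered as 9.59 on average and called in 20 of 20 simulations, and no added overlap was called in 0 of 20. The list with no added overlap was itself a rotated list, so it met the assumption of the test by construction. Simulated losses were drawn peak by peak from the score decile, without regional clustering, and gain was not simulated. How often clustered losses would be called was therefore not tested. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.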

Results

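The series examined the roles of Tet2, the transcription factor Foxo3a and cytosine modifications in neurogenesis. Foxo3a is a forkhead factor known for its part in the maintenance of adult neural stem cells. The lists analysed came from proliferating neural stem cells. They held 170335 5hmC peaks in wild-type cells, 116616 5hmC peaks in Tet2 -/- cells, and 21395 merged Foxo3a regions from both genotypes. The 5hmC peaks had a median width of 565 bp in wild-type and 557 bp in Tet2 -/- cells. Foxo3a regions were narrower, with a median of 99 bp. None of the lists gave replicate values, so differences between genotypes below have no replicate check, and sequencing depth is unknown.

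The first comparison asked how the 5hmC peak lists of wild-type and Tet2 -/- cells differed in number and distribution. The Tet2 -/- list held 31.5% fewer 5hmC peaks than the wild-type list, a ratio of 0.685. The genomic length covered by 5hmC peaks was 112 Mb in wild-type and 73.7 Mb in Tet2 -/- cells, a ratio of 0.660, with mean peak widths of 656 and 632 bp. All 19 autosomes had fewer peaks in Tet2 -/- cells, and their ratios ranged from 0.630 on chromosome 1 to 0.735 on chromosome 7, with a median of 0.693. The X chromosome carried few 5hmC peaks in either genotype, 11.2 per Mb in wild-type and 7.58 per Mb in Tet2 -/- cells. The median autosome carried 69.3 and 47.5 per Mb, which was 6.16 and 6.27 times the density of the X chromosome. Density was not adjusted for the copy number of X, and both lists also held peaks on Y (38 in wild-type and 26 in Tet2 -/- cells). The ratio of Tet2 -/- to wild-type peaks on X was 0.675, within the range of the autosomes. On X, 46.0% of wild-type and 19.8% of Tet2 -/- peaks there had no counterpart, against autosomal ranges of 35.4 to 42.6% and 6.74 to 12.4%.

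**Figure D1:**
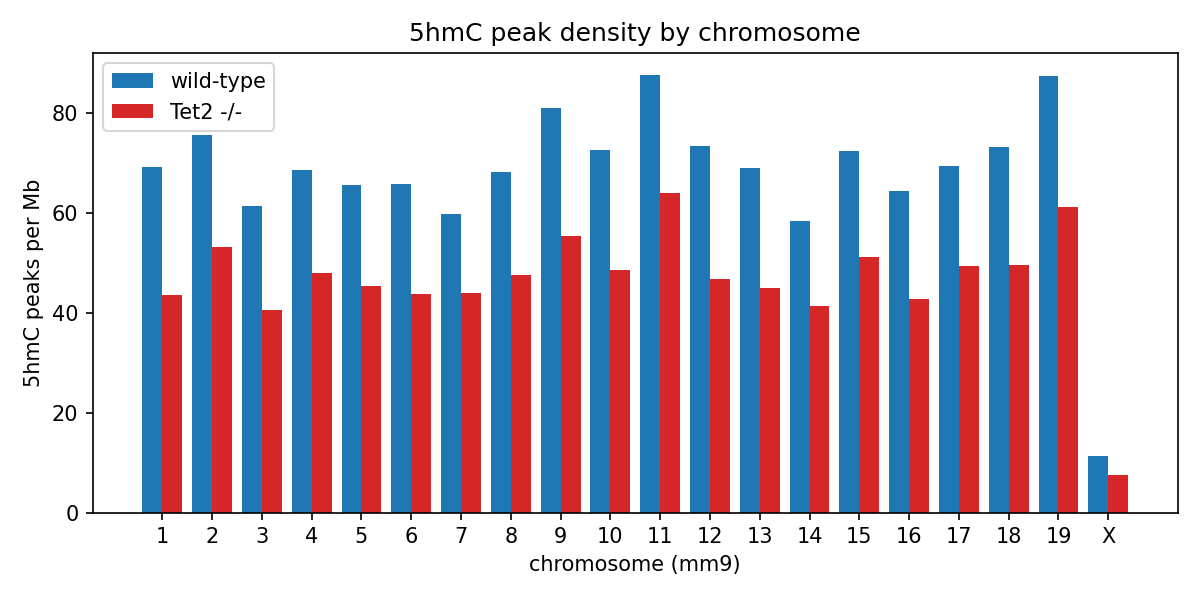
5hmC peaks per Mb of each mm9 chromosome (vertical axis) for chromosomes 1 to 19 and X (horizontal axis), with 1 bar per genotype and no error bars because each genotype has 1 list. Every chromosome shown has a lower Tet2 -/- bar, and X stands far below the autosomes in both genotypes.

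Most windows held fewer 5hmC peaks in Tet2 -/- cells. Of the 2334 windows of 1 Mb with any 5hmC peak, 2194 held fewer peaks in Tet2 -/- cells, 69 held more and 71 held equal numbers. Among the 1391 windows with at least 50 peaks in either list, 1387 held fewer and 4 held more, and the median log2 ratio was -0.52 with quartiles of -0.65 and -0.39. The largest relative losses were in windows of chromosome 9 at 28000001-29000000, where 59 wild-type peaks faced 19 Tet2 -/- peaks (log2 ratio -1.42), and of chromosome 2 at 106000001-107000000, with 54 and 18 peaks (log2 ratio -1.36). The window of chromosome 2 at 169000001-170000000 had 113 wild-type and 42 Tet2 -/- peaks. The remaining 2 of the 5 windows with the largest loss were on chromosome 16 at 73000001-74000000, with 52 and 18 peaks, and on chromosome 18 at 66000001-67000000, with 71 and 26 peaks. At the other end, neighbouring windows of chromosome 8 held slightly more peaks in Tet2 -/- cells. The window at 72000001-73000000 had 94 wild-type and 103 Tet2 -/- peaks (log2 ratio 0.13), and the window at 73000001-74000000 had 100 and 103. Chromosome 2 at 180000001-181000000 held 53 and 55 peaks, chromosome 7 at 150000001-151000000 held 72 and 73, and chromosome 7 at 29000001-30000000 held 97 and 96. The 5 windows with the largest loss contained 1 to 11 Foxo3a regions each, and the 5 at the upper end contained 13 to 60. In the order given, the windows with the largest loss held 2, 7, 8, 1 and 11 Foxo3a regions. The median autosome held 9.53 Foxo3a regions per Mb, which is below all 5 windows at the upper end.

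The next comparison asked which 5hmC peaks were held in common. Of the Tet2 -/- peaks, 105657 (90.6%, 95% interval 90.4 to 90.8) overlapped a wild-type peak. Of the wild-type peaks, 103862 (61.0%, 95% interval 60.7 to 61.2) overlapped a Tet2 -/- peak. Rotation of the Tet2 -/- list gave 8.45% and 5.83%, and both observed shares exceeded every rotation (rotation permutation p = 0.002, the smallest possible). A total of 66473 wild-type peaks had no Tet2 -/- counterpart and 10959 Tet2 -/- peaks had no wild-type counterpart, a ratio of 6.07. With the lists limited to equal numbers of peaks by score these became 26402 and 23436, a ratio of 1.13, which equal list lengths hold near 1. With scores at or above the median of each list the ratio was 5.73, but this setting keeps the ratio of list lengths at 0.685. With both lists limited to scores of at least 100 it was 7.21, and with such peaks set against the whole other list it was 12.1, although a fixed score is not comparable between lists of unknown depth. The lists had 63.6 Mb in common, which was 86.2% of the Tet2 -/- length and 56.9% of the wild-type length.

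Peaks found in 1 genotype were weaker and narrower than shared peaks of the same list. Wild-type peaks without a Tet2 -/- peak had a median score of 79.3 (quartiles 61.4 and 114) and a median width of 466 bp, against a score of 241 and a width of 657 bp for shared wild-type peaks. Tet2 -/- peaks without a wild-type peak had a median score of 66.4 and a width of 432 bp, against 146 and 573 bp for shared ones. In the lowest score decile of the wild-type list 18.5% of peaks were shared, in the fifth 54.0%, and in the highest 99.9%. The Tet2 -/- list ran from 70.2% in its lowest decile to 99.98% in its highest. Among peaks with a score of at least 100, 21672 of 108654 wild-type peaks (19.9%) and 1785 of 71702 Tet2 -/- peaks (2.49%) had no counterpart. Of the wild-type peaks with a score of 500 or more, 61 of 23826 had none, and of such Tet2 -/- peaks 2 of 14695.

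**Figure D2:**
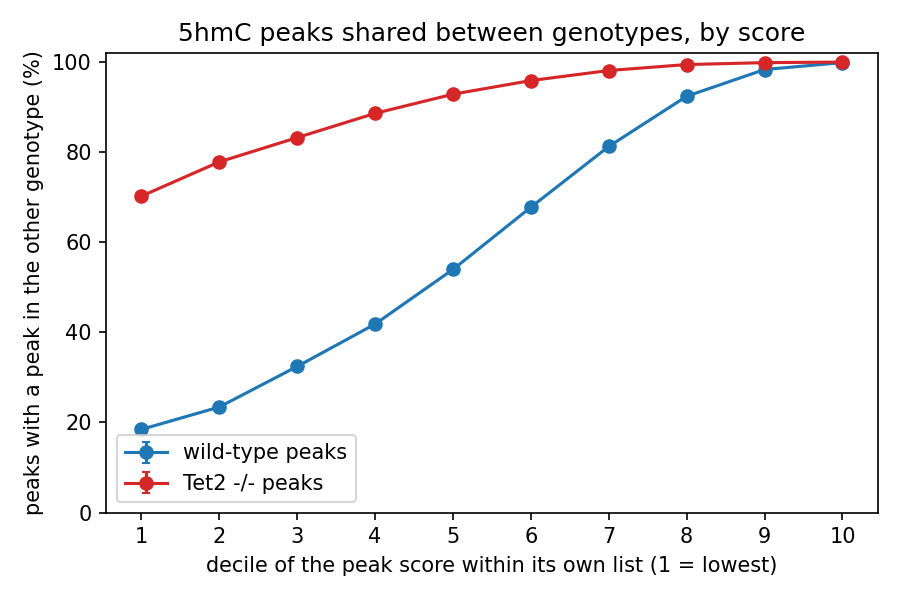
Share of 5hmC peaks that overlap a peak of the other genotype (vertical axis, percent) by decile of the peak score within its own list (horizontal axis), with exact 95% binomial intervals that are mostly smaller than the points. Sharing rises from 18.5% to 99.9% over the wild-type deciles and from 70.2% to 99.98% over the Tet2 -/- deciles.

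The highest-scoring 5hmC peaks of each genotype had a counterpart in the other. The 5 highest-scoring wild-type peaks lay on chromosome 11 at 107637939-107641324, chromosome 12 at 101552684-101555022, chromosome 11 at 88465615-88468365, chromosome 1 at 138037734-138040859 and chromosome 16 at 33882616-33884656. Their scores were 3210 to 3233, and 5 of 5 overlapped a Tet2 -/- peak. The 5 highest-scoring Tet2 -/- peaks lay on chromosome 10 at 39224532-39227169, chromosome 2 at 166516828-166518583, chromosome 15 at 58818841-58820979, chromosome 9 at 50660370-50661709 and chromosome 3 at 105370973-105371973, and 5 of 5 overlapped a wild-type peak. The highest-scoring wild-type peak without a counterpart, named after its value was seen, was on chromosome 14 at 34633491-34634728, 1238 bp wide with a score of 1163. The highest-scoring Tet2 -/- peak without a counterpart, also named after its value was seen, was on chromosome 17 at 53726264-53727388, 1125 bp wide with a score of 613.

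The third comparison placed 5hmC relative to Foxo3a binding. Of the 21395 Foxo3a regions, 3088 (14.4%, 95% interval 14.0 to 14.9) overlapped a wild-type 5hmC peak and 3269 (15.3%, 95% interval 14.8 to 15.8) overlapped a Tet2 -/- 5hmC peak. Rotated Foxo3a regions gave 5.38% and 3.60%, so the observed overlap was 2.68-fold and 4.24-fold over rotation (rotation permutation p = 0.002 each, the smallest possible). Foxo3a regions were split into 2400 with 5hmC peaks in both genotypes, 688 with a wild-type peak only, 869 with a Tet2 -/- peak only and 17438 with neither. The ratio of the Tet2 -/- to the wild-type overlap was 1.06, against 0.669 for rotated Foxo3a regions (rotation permutation p = 0.002). Local shifts of 20 to 200 kb as the reference lowered the folds to 1.52 and 2.23 (rotation permutation p = 0.002 each). The raw difference of 0.846 percentage points in favour of Tet2 -/- turned to -0.594 points among 5hmC peaks with a score of at least 100. With equal numbers of 5hmC peaks in both lists it was 3.26 points. The 2079 Foxo3a regions that joined peaks of both underlying peak lists overlapped wild-type 5hmC at 5.68%, which was 0.951 times rotation (rotation permutation p = 0.683), and Tet2 -/- 5hmC at 8.80%, which was 2.20 times rotation (rotation permutation p = 0.002).

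Around Foxo3a midpoints, Tet2 -/- 5hmC was highest at the midpoint itself and wild-type 5hmC was highest to the side. Tet2 -/- peaks covered 13.9% of midpoints, an average of 11.6% of positions 500 to 1000 bp away and 7.41% of positions 4500 to 5000 bp away. Wild-type peaks covered 13.2% of midpoints, 14.0% of positions 500 to 1000 bp away and 9.96% of positions 4500 to 5000 bp away. Their coverage also had a small local rise at the midpoint, from 12.5% at 400 bp on either side. Tet2 -/- peaks without a wild-type counterpart covered 2.30% of midpoints and 0.571% of positions 4500 to 5000 bp away, and wild-type peaks without a Tet2 -/- counterpart covered 1.87% and 2.26%.

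**Figure D3:**
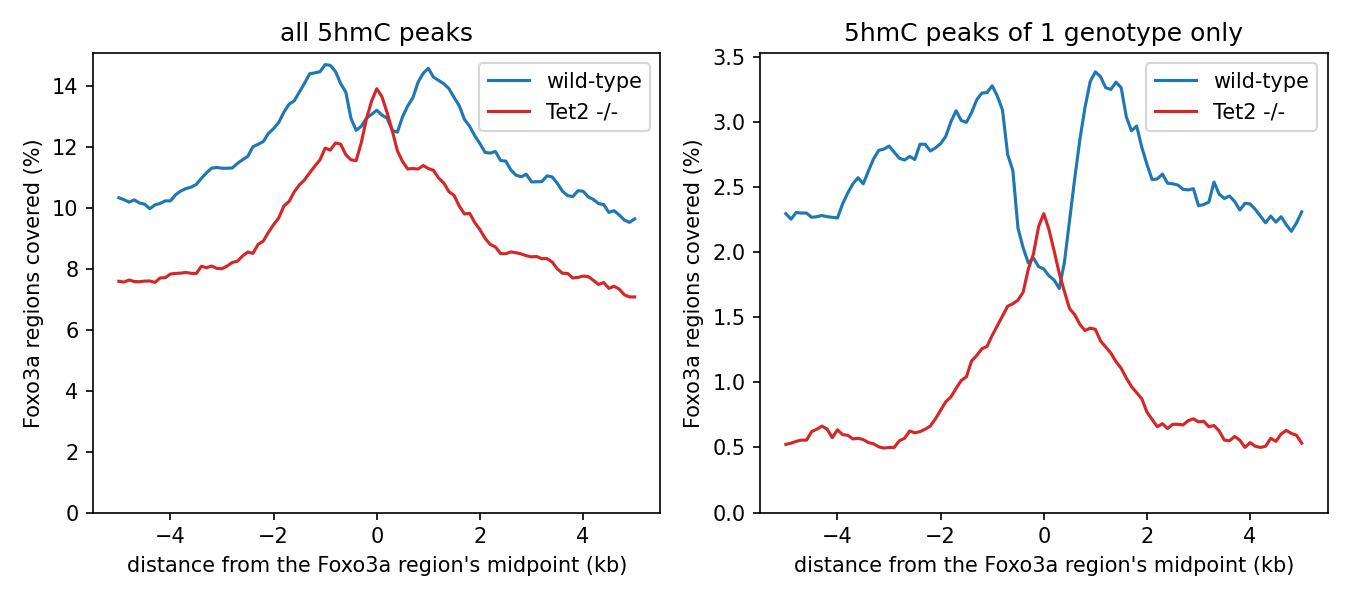
Share of Foxo3a regions (vertical axis, percent) whose position at a given distance in kb from the region's midpoint (horizontal axis) is covered by a 5hmC peak, for all 5hmC peaks on the left and for peaks of 1 genotype only on the right. The Tet2 -/- lines peak at the midpoint, at 13.9% on the left and 2.30% on the right, where the wild-type-only line dips.

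The windows richest in Foxo3a regions were on chromosome 10 at 80000001-81000000 with 89 regions and at 79000001-80000000 with 82, on chromosome 7 at 52000001-53000000 with 65, on chromosome 9 at 3000001-4000000 with 64 and on chromosome 11 at 3000001-4000000 with 63. The chromosome 10 windows held 136 and 135 wild-type and 126 and 119 Tet2 -/- 5hmC peaks. The chromosome 7 window held 97 and 86, and the chromosome 11 window 92 and 82. The chromosome 9 window held 0 wild-type and 4 Tet2 -/- 5hmC peaks. No filter for repeats was applied to the lists here. Mapping artefacts were therefore not excluded, in particular for the chromosome 9 and chromosome 11 windows near a chromosome end. Foxo3a regions were also sparse on X, at 2.05 per Mb against 9.53 per Mb on the median autosome.

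The last comparison asked whether 5hmC peaks were lost or gained at Foxo3a regions as often as elsewhere. Among the 2868 wild-type 5hmC peaks that overlapped a Foxo3a region, 450 (15.7%, 95% interval 14.4 to 17.1) had no Tet2 -/- peak. Among the other 167467 wild-type peaks, 66023 (39.4%) had none. The odds ratio was 0.286, against a median of 0.705 for rotated Foxo3a regions (rotation permutation p = 0.002; Fisher's exact p = 1.13e-166, which treats peaks as independent). Wild-type peaks at Foxo3a regions were stronger and wider than the rest, with a median score of 258 against 139 and a median width of 792 against 562 bp. Within deciles of score and width the odds ratio was 0.388 (chromosome jackknife interval 0.343 to 0.439, rotation permutation p = 0.002). It was 0.500 among 5hmC peaks with scores at or above the median of their list. With only Foxo3a regions joined from both underlying peak lists it was 0.209. That value rested on 19 of 115 wild-type peaks without a counterpart, and the odds ratio without deciles was 0.316 there.

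The opposite class was more frequent at Foxo3a. It was counted from the same 3 lists as the overlap, the coverage around midpoints and the loss, so these results are not independent of each other. Among the 2939 Tet2 -/- 5hmC peaks that overlapped a Foxo3a region, 489 (16.6%, 95% interval 15.3 to 18.0) had no wild-type peak, against 10470 (9.21%) of the other 113677. The odds ratio was 1.97, against a median of 0.767 over rotations (rotation permutation p = 0.002), and within deciles of score and width it was 3.49 (chromosome jackknife interval 3.04 to 4.01, rotation permutation p = 0.002). The 2 odds ratios were 1.24 and 2.04 among 5hmC peaks with scores at or above the median of their list, and 5.40 and 7.25 for Foxo3a regions joined from both underlying peak lists. The values of 5.40 and 7.25 rested on 60 of 168 Tet2 -/- peaks without a counterpart. Within deciles, the central 95% of rotations of those regions ran from 0.274 to 2.29. In the fifth score decile of the Tet2 -/- list, 25.1% of peaks at Foxo3a regions and 6.70% of the others had no wild-type peak. In the fifth score decile of the wild-type list, 21.8% of peaks at Foxo3a regions and 46.4% of the others had no Tet2 -/- peak.

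The wild-type difference narrowed with distance from Foxo3a out to 50 kb, and its values lay above 1 beyond that. The Tet2 -/- difference narrowed out to 5 kb, and its values lay below 1 from 5 to 200 kb and near 1 beyond. The expectation came from the same list, so a departure near Foxo3a must be offset at other distances. Relative to the share expected from score and width, wild-type peaks without a counterpart were at 0.620 of expectation where they overlapped a Foxo3a region, at 0.794 within 1 kb, at 0.90 from 1 to 5 kb, at 0.986 from 5 to 50 kb, at 1.05 from 50 to 200 kb and at 1.08 beyond 200 kb. Tet2 -/- peaks without a counterpart were at 2.40, 1.57, 1.07, 0.964, 0.856 and 1.01 of expectation in the same classes.

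**Figure D4:**
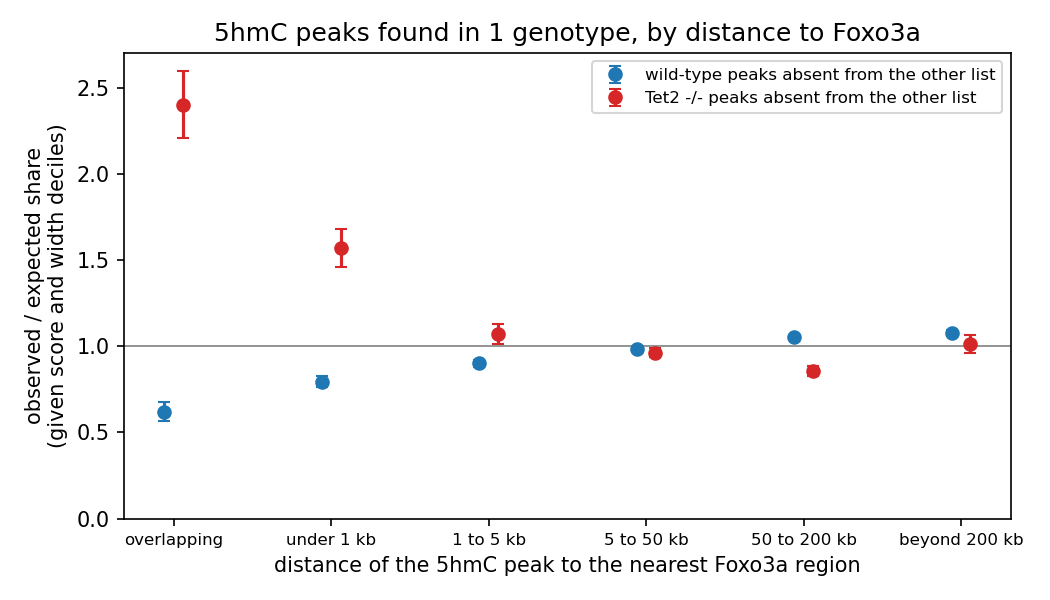
Observed over expected share of 5hmC peaks that are absent from the other genotype's list (vertical axis, expectation from deciles of score and width) by distance of the peak to the nearest Foxo3a region (horizontal axis), with exact 95% binomial intervals divided by the expectation. At Foxo3a regions the wild-type value is 0.620 and the Tet2 -/- value 2.40, and from 5 to 50 kb they are 0.986 and 0.964.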

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

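The peak names in the Foxo3a list, which the comparisons did not use except as a subset, hold a further signal, and this reading of them was chosen after seeing the data. The 23806 names fall into 2 unbroken numbering series of 12479 and 11327 peaks, as from 2 separate peak lists, and nothing says which series belongs to which genotype. Only 2079 of the 21395 merged regions (9.72%, 95% interval 9.32 to 10.1) hold names of both series, and these account for 18.9% of all peak names. A 5hmC peak of either genotype overlapped 10.0% (95% interval 8.75 to 11.4) of the regions of both series and 19.4% (95% interval 18.9 to 20.0) of the other 19316. Regions of both series are joined from at least 2 peaks, so they are wider by construction. Each genotype has 1 Foxo3a library, so spread between libraries cannot be separated from genotype.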

How the results depend on the processing

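Of 119 results under alternatives, 112 kept their direction and their side of the threshold or moved within the counting interval. Some of the 112 values could not move, so the count overstates stability. The ratio of peak numbers is fixed when the upper part of each list by its median score is taken. Local shifts change only the reference, so observed shares, the raw difference and odds ratios stayed the same and only their rotation p could change. The ratio of Tet2 -/- to wild-type peak number moved from 0.685 to 0.660 at a score of at least 100 and to 0.709 after merging peaks within 500 bp, and it is 1 by construction with equal numbers of peaks. With equal numbers, 77.4% of wild-type and 79.9% of Tet2 -/- peaks were shared. Over the alternatives the shared percentages ranged from 58.6 to 77.4 for wild-type and from 79.9 to 92.8 for Tet2 -/- peaks. The raw difference in Foxo3a overlap, Tet2 -/- minus wild-type in percentage points, reversed from 0.846 to -0.603 with scores at or above each list's median, to -0.594 with a score of at least 100 and to -1.01 with peaks counted within 500 bp. The cause of these reversals was not tested. The raw difference kept its sign in 9 of 12 alternatives and was largest, at 3.26 points, with equal numbers of 5hmC peaks. The same comparison relative to rotation ranged from 1.39 to 2.31 and did not change side. Local shifts lowered the Foxo3a overlap from 2.68-fold to 1.52-fold for wild-type and from 4.24-fold to 2.23-fold for Tet2 -/- 5hmC peaks. With Foxo3a regions named in both series, chosen after seeing the data, the wild-type overlap reversed to 0.951 of rotation (118 regions), and the cause was not tested. The odds ratio within deciles ranged from 0.209 to 0.500 for loss and from 2.04 to 7.25 for gain at Foxo3a. The values of 0.209 and 7.25 came from Foxo3a regions named in both series, which overlapped only 115 wild-type and 168 Tet2 -/- 5hmC peaks.

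The alternatives for gene bodies and genomic features were not run, since no mm9 annotation was used. No paired analysis was possible because each genotype has 1 5hmC list without values per replicate, and leaving out a replicate was not possible for the same reason. The unknown depth limits the comparison of list lengths.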

Other observations

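Some regions stood apart in 1 of the assays and were picked after their values were seen. The widest Foxo3a region was on chromosome 17 at 39979936-39983328 (3393 bp), and the next 3 were on chromosome 11 between 3042696 and 3093959, near the centromeric end of the chromosome. The fifth widest lay at the far end of X at 166426480-166427633, next to the widest Tet2 -/- 5hmC peak, X at 166414774-166422045 (7272 bp, score 162.9). The mitochondrial genome held 3 Foxo3a regions and 0 5hmC peaks of either genotype. Whether these wide or mitochondrial Foxo3a regions are mapping artefacts was not tested, since no filter for repeats was applied. The Y chromosome held 38 wild-type and 26 Tet2 -/- 5hmC peaks and 0 Foxo3a regions. The densest 5hmC windows were on chromosome 12 at 54000001-55000000, with 306 wild-type and 180 Tet2 -/- peaks, and on chromosome 7 at 56000001-57000000, with 281 and 204. They held 7 and 10 Foxo3a regions. Wild-type peaks without a counterpart lay a median of 3.18 kb (quartiles 0.949 and 9.35) from the nearest Tet2 -/- peak, and 15.9% lay within 500 bp of one.

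The tests weighed below had their outcomes set out before the tested values were seen, but the patterns themselves were found in these lists. The correlation over windows was chosen afterwards.

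Fewer wild-type 5hmC peaks were without a Tet2 -/- peak at Foxo3a regions. Differences in peak score and width do not account for the whole pattern, since the odds ratio within their deciles was 0.388 with a jackknife interval of 0.343 to 0.439. The regional setting was tested against peaks 5 to 50 kb from a Foxo3a region, where the odds ratio was 0.405 (0.360 to 0.456). A smaller regional part remains, with an odds ratio of 0.813 for peaks 5 to 50 kb away against those farther. Local base composition and chromatin opening at Foxo3a sites were not tested, and they stay open, as does the genotype itself. With 1 list per genotype, a difference in depth or recovery between the 5hmC libraries also stays open and was not tested.

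More Tet2 -/- 5hmC peaks were without a wild-type peak at Foxo3a regions. The odds ratio was 3.49 (3.04 to 4.01) within deciles of score and width and 3.56 (3.10 to 4.09) against peaks 5 to 50 kb away, so neither accounts for the whole pattern. For peaks 5 to 50 kb away against those farther the odds ratio was 1.1 (1.01 to 1.20), but the shares showed no steady regional trend. Relative to expectation they were 0.964 from 5 to 50 kb, 0.856 from 50 to 200 kb and 1.01 beyond 200 kb. With 1 list per genotype, the genotype and a difference in recovery between the 5hmC libraries both stay open and were not tested, and base composition was not tested either.

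The wild-type 5hmC list was longer than the Tet2 -/- list. A difference in depth or detection limit that acts alike over the genome could be a candidate explanation. It would spread the missing peaks at random once score and width are given, if peaks were lost independently of their neighbours. The spread over 1391 windows was 2.87, against at most 1.13 in 1000 random reassignments, a ratio of 2.55. This was the outcome set beforehand as going against it. The reassignments took peaks as independent within deciles, however, so neighbours of like detectability would also widen the spread. The test therefore cannot decide whether such a difference is the whole cause. The missing share per window, relative to expectation, fell with the number of Foxo3a regions (Spearman's rho -0.43 across windows, rotation p = 0.002, the smallest possible), also for 5hmC peaks 5 kb or more from any Foxo3a region (rho -0.37, rotation p = 0.002). Windows are not independent replicates. Depth or recovery, whether alike over the genome or different between regions, stays open beside the genotype itself.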
